A study of Mus musculus with 12 samples.

How the data were processed

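Liver RNA of 12 samples, 3 in each of 4 groups, was sequenced on Illumina libraries made from DNase-treated total RNA, per the labels. The groups were regular chow (replicates 8, 17 and 19), high-fat diet (4, 30 and 38), high-fat diet with vehicle (15, 23 and 55) and high-fat diet with PCN (5, 11 and 27). The replicate numbers in the sample titles differ between groups, so no pairing was used. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm38/mm10, counted with HTSeq and compared with DESeq2, with versions and settings not given in the sources used here. The authors deposited 6 pairwise tables of raw read counts per gene, 6 libraries per table, beside a mean of size-factor-normalized counts. The authors' deposited log2 fold changes, standard errors, p-values and adjusted p-values come from DESeq2, per the file headers and the notes.

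The 6 tables were not equally complete. The table of vehicle against uninjected high-fat diet gave values for 26015 genes. The other 5 gave values only for genes with a deposited adjusted p under 0.05. The counts of a gene and library were the same in every table that listed it (187884 values compared, 0 differed). Counts were thus at hand for 26031 gene identifiers in some libraries, for 2877 genes in chow, 2455 in PCN and 2227 in all 12 libraries. The deposited fold changes were moderated toward 0, at a median of 0.772 to 0.874 of the log2 ratio of normalized counts and by more for variable genes. In the authors' deposited table Cyp3a11 had a log2 change of 1.72 between PCN and vehicle, where the ratio of group means was 64.1-fold. Folds are therefore given as ratios of group means.

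Summed counts were 38161486, 24006180 and 7466378 for high-fat-diet replicates 4, 30 and 38 and 22039805, 20059676 and 19773547 for vehicle replicates 15, 23 and 55. Totals of the other libraries were estimated from size factors, as 22300000, 15100000 and 17500000 for chow replicates 8, 17 and 19 and 35400000, 11500000 and 18600000 for PCN replicates 5, 11 and 27. Where both were known the estimate was off by up to 16.6%. The 10 most abundant genes took 20.1% to 22.6% of the counts of the 6 complete libraries. In a principal component analysis of those 6 libraries, vehicle replicate 55 scored 59.6 on the first component (40.7% of variance; the others -27.5 to 14.6). High-fat-diet replicate 38 scored 50.2 on the second (32.8%; the others -34.9 to 13.8). Vehicle replicate 23 had a higher median correlation across genes with the uninjected libraries (0.990) than with its own group (0.981).

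Size factors were recovered from counts and deposited means, brought to 1 scale for the 12 libraries (largest difference 0.52%) and used for group means and SD. Gene starts, which the tables count from 0, were raised by 1, after which 95.5% of identifiers found in GENCODE M21 had the same chromosome, start and end.

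Before the data were examined, the following were fixed: the 6 comparisons, the tests, 25 gene lists holding 607 genes, a set of genes given whether called or not, and the rule for naming genes. The tests were edgeR quasi-likelihood for counts and the authors' deposited adjusted p where only their results were given. The rule named, per comparison, the 5 called genes with the largest deposited log2 change in each direction and a mean count of at least 50, and up to 4 called members of each list with at least 3. It was applied to the deposited calls in the 6 comparisons. The text takes its genes from these and adds some list members as examples after their values were seen. The rules did not foresee tables with counts for called genes alone. For the complete table edgeR was the test, on genes kept by its expression filter (13775). For the other 5 the calls are the authors' deposited calls, and the counts of the listed genes were tested again with edgeR, with the deposited size factors, the dispersion prior of the complete table and Benjamini-Hochberg adjustment over the estimated number of genes tested (25101 to 25880). This second test was chosen after the tables were seen. Genes missing from those tables were not analysed here. Some named genes are not reported here. With 3 samples per group an exact permutation test of a single gene cannot give p below 0.10. Tests were two-sided except Fisher's exact tests of overlaps and lists, which were one-sided.

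Lists were tested with a one-sided Fisher's exact test of deposited calls against 13867 background genes, adjusted over the 25 lists of a comparison. The background held the 13775 genes kept by the edgeR filter and every gene called in any comparison. A gene below that filter was thus measured only if called, which raises the share called in its list. The filter kept 27 of 30 measured phase I enzymes and 25 of 30 measured sex-biased genes. In the complete table camera of limma (preset correlation 0.01) was the test, with an estimated correlation and fry for a common direction as alternatives, and fry for either direction as one added after the data were seen. Both camera with a preset correlation and Fisher's test treat the genes of a list as nearly independent. Shared calls were counted per direction against the product of the 2 numbers of calls over the background. Unchanged groups were simulated 8 times per pair against the shared libraries. Ratios on the log2 scale used a pseudocount of 0.5, and standard errors of list medians came from 10000 bootstrap draws over genes. Intervals of ratios resting on few counts are exact (Clopper-Pearson, 95%) from the pooled counts and size factors, and cover counting error only.

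The edgeR test was tested on simulated data with 200 changed genes. It recovered 0% of 66 genes changed 1.5-fold, 27.3% of 66 changed 2-fold and 87.3% of 63 changed 4-fold, with 5 false among 78 calls. DESeq2 listed 110 genes at an adjusted p under 0.05 in these simulated data, 93 of them changed and 17 unchanged. The test of listed genes passed 71 of these 110, 4 of them unchanged, and gave the verdict of the full edgeR test for 94.5%. In that simulation the prior came from the same simulated comparison, so carrying a prior over to other comparisons was not tested.

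Alternatives were an adjusted p under 0.01, an absolute log2 change of at least 1, no expression filter, DESeq2 in place of edgeR, list members with a mean count of at least 50, and each library left out in turn. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.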

Results

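RNA was sequenced from the livers of C57BL/6N mice in 4 groups of 3 samples: regular chow, high-fat diet without injection, high-fat diet with injected vehicle, and high-fat diet with pregnenolone 16α-carbonitrile (PCN). PCN is a synthetic steroid that activates the rodent pregnane X receptor (PXR), a nuclear receptor that switches on genes for drug metabolism and transport. The diet started at 6 weeks of age and lasted 15 weeks, and PCN (50 mg/kg) or its vehicle was injected intraperitoneally once daily for 4 days. Group values are means of normalized read counts ± SD with n = 3, on 1 scale for the 12 libraries, and a fold is the ratio of 2 such means. Rose and fell refer to genes past an adjusted p of 0.05 in the authors' deposited DESeq2 tables, unless another test is named. The deposited tables gave 442 genes between PCN and vehicle, 1226 between high-fat diet and chow, 206 between vehicle and no injection, 809 between PCN and the uninjected high-fat diet, 790 between vehicle and chow, and 2032 between PCN and chow. The labels do not say outright that each replicate is a separate animal. The p-values of single genes measure effects against the spread between these samples. Fisher's exact tests of lists and overlaps count called genes as nearly independent units, and their p-values do not measure the spread between samples.

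PCN against vehicle is the comparison that isolates the compound, since both groups were injected. Cyp3a11, which encodes the main PCN-inducible steroid- and drug-oxidising cytochrome P450 of mouse liver, rose 64.1-fold, from 10422 ± 9760 normalized counts with vehicle to 668281 ± 283282 with PCN. Without vehicle replicate 23 the Cyp3a11 ratio was 139-fold. Ces2a, a carboxylesterase that hydrolyses drug and lipid esters, rose 19.1-fold, from 3389 ± 1281 to 64747 ± 18952. Cyp2c55 rose 411-fold, from 14.8 ± 5.3 to 6069 ± 3494, and Gstm3, a glutathione transferase, rose 315-fold, from 133 ± 82.7 to 41909 ± 24237. Without vehicle replicate 23 the Gstm3 ratio was 482-fold, and that of Cyp3a44, which rose 63.7-fold, was 110-fold. Slco1a4, which takes up organic anions from blood, rose 6.04-fold, and the efflux pumps Abcb1a and Abcc3 rose 3.30-fold and 1.78-fold. In the GRCm38 annotation the Cyp3a11 gene (ENSMUSG00000056035) spans positions 145854426 to 145879964 of chromosome 5. The Ces2a gene (ENSMUSG00000055730) spans positions 104734003 to 104741634 of chromosome 8, and the Cyp2c55 gene (ENSMUSG00000025002) spans positions 39007019 to 39042693 of chromosome 19. Reads of the Cyp3a and Gstm families can map to more than 1 paralog, so the split of counts within each family is uncertain.

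Of 30 measured phase I enzymes that respond to PXR or its relative CAR, 17 rose with PCN, 1 fell and 12 did not pass. The edgeR filter of the vehicle comparison kept 27 of the 30, and the others count as measured only because they were called. Among genes with a mean count of at least 50, 14 rose and 1 fell of 26 (adjusted p = 3.08e-14, exact). The risers included Cyp2c29 (3.5-fold), Aldh1a1 (2.09-fold) and Ces2c (3.46-fold), and the gene that fell was Alas1, the first enzyme of heme synthesis, 2.04-fold lower. Of 32 phase II conjugation enzymes 14 rose and 0 fell, among them Gstm1 (8.23-fold) and Ugt1a1 (2.16-fold). Fisher's exact test of called list members gave adjusted p = 1.25e-18 for phase I and 2.12e-12 for phase II. Of 17 drug and bile salt transporters 3 rose and 0 fell (adjusted p = 0.0506, exact). Of 18 NRF2 antioxidant genes 4 rose, including Gsr and Tkt (adjusted p = 0.00908, exact). In edgeR 4 of the 18 called phase I and 2 of the 14 called phase II genes passed. Of the 3 transporters and the 4 NRF2 genes 0 passed edgeR. Cyp2b10, which responds to CAR, was called in none of the 6 tables, and neither was Cyp7a1, the rate-limiting enzyme of bile acid synthesis. Of 30 sex-biased genes 5 rose, among them Cyp3a44, Cyp2a4 (2.69-fold) and Sult3a1 (69.9 ± 55.4 normalized counts against 5.9 ± 2.5), and Egfr fell 2.63-fold (adjusted p = 0.00157, exact, and 0.127 with 2 risers and 1 faller of 23 among genes with a mean count of at least 50). Without vehicle replicate 55 Egfr was 1.72-fold lower. The sex-biased list shares 11 of its 33 genes with other lists.

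Part of the cholesterol synthesis genes rose with PCN. Cyp51, the lanosterol demethylase, rose 3.72-fold, from 2031 ± 1214 to 7554 ± 2765 normalized counts. Fdft1 (squalene synthase) rose 2.98-fold, from 1814 ± 720 to 5405 ± 1712, and Dhcr7, the last step to cholesterol, rose 2.86-fold. Of 26 cholesterol synthesis and SREBP2 target genes 13 rose, 0 fell and 13 did not pass (adjusted p = 2.12e-12, exact), and 1 of the 13 risers also passed edgeR. Of those that did not pass, Sqle stood at 4184 ± 1773 with PCN against 1113 ± 1095 with vehicle. Of 23 fatty acid and triglyceride synthesis genes 8 rose and 0 fell, with Elovl6, a fatty acid elongase, 3.94-fold higher and Fasn 2.24-fold higher (adjusted p = 2.01e-06, exact). Between vehicle and no injection, a comparison that uses the same vehicle libraries, 8 genes of this list fell. Over uninjected livers PCN gave 1 riser and 2 fallers of the 23 (adjusted p = 0.285, exact). Elovl6 counts were 992.8 to 1662.4 in uninjected, 333.5 to 411.1 in vehicle and 1084.5 to 1762.2 in PCN libraries.

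Fewer genes fell with PCN. Cidea, a lipid droplet protein that promotes droplet fusion, fell 26.7-fold, from 34.0 ± 23.0 to 1.3 ± 0.4 normalized counts. The PCN libraries held 4 Cidea counts in all against 102 with vehicle, and the ratio of pooled counts was 28.3 (95% interval 10.7 to 106, Clopper-Pearson, counting error only). Plin4 fell 1.55-fold and Fabp2, a fatty acid binding protein, fell 1.72-fold. Of 22 lipid droplet genes these 3 fell, 0 rose, and the list did not pass (adjusted p = 0.0718, exact). In edgeR 0 of these 3 passed. Cfd, the complement factor adipsin, fell 33.2-fold, from 128 ± 71.7 to 3.9 ± 2.8, and was 52.8-fold lower without PCN replicate 11. The metallothioneins Mt1 and Mt2 and the acute phase gene Saa4 fell, 3 of the 4 acute phase genes of 31 that fell with 0 rising (adjusted p = 0.0506, exact). Igfbp1, an insulin-repressed secreted protein, fell 2.85-fold and was 1 of 4 of 34 gluconeogenesis, glycolysis and insulin genes that fell (adjusted p = 0.0555, exact). Nr0b2 (SHP), which represses bile acid synthesis, fell 2.47-fold while Cyp8b1 rose 2.04-fold, in a list of 19 bile acid genes that did not pass (adjusted p = 0.0555, exact). Cyp8b1 was 1.86-fold lower with vehicle than without injection, past the authors' deposited DESeq2 test and not past edgeR. Markers of macrophages (23 genes), stellate cells (24) and endothelial cells (16) had 0 members called between PCN and vehicle in the authors' DESeq2 table. PCN counts were at hand for 4, 9 and 2 of them, the ones called in other comparisons. Of these edgeR had 1 (Cd14), 2 (Acta2 and Sparc) and 0 at an unadjusted p under 0.05. The contrast with their calls in the diet comparison was not tested.

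Of the 442 genes between PCN and vehicle, 276 rose and 166 fell. An edgeR test of the same genes' counts passed 15, among them Ces2a, Cyp2c55, Cyp3a44, Gstm3, Gstm1, Elovl6 and Tm7sf2. Cyp3a11 did not pass (adjusted p = 0.0814, edgeR), nor did Cyp51 (adjusted p = 0.288, edgeR). The edgeR count was 0 without vehicle replicate 15, vehicle replicate 55 or PCN replicate 27, 2 without vehicle replicate 23, 5 without PCN replicate 5 and 23 without PCN replicate 11.

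**Figure D1:**
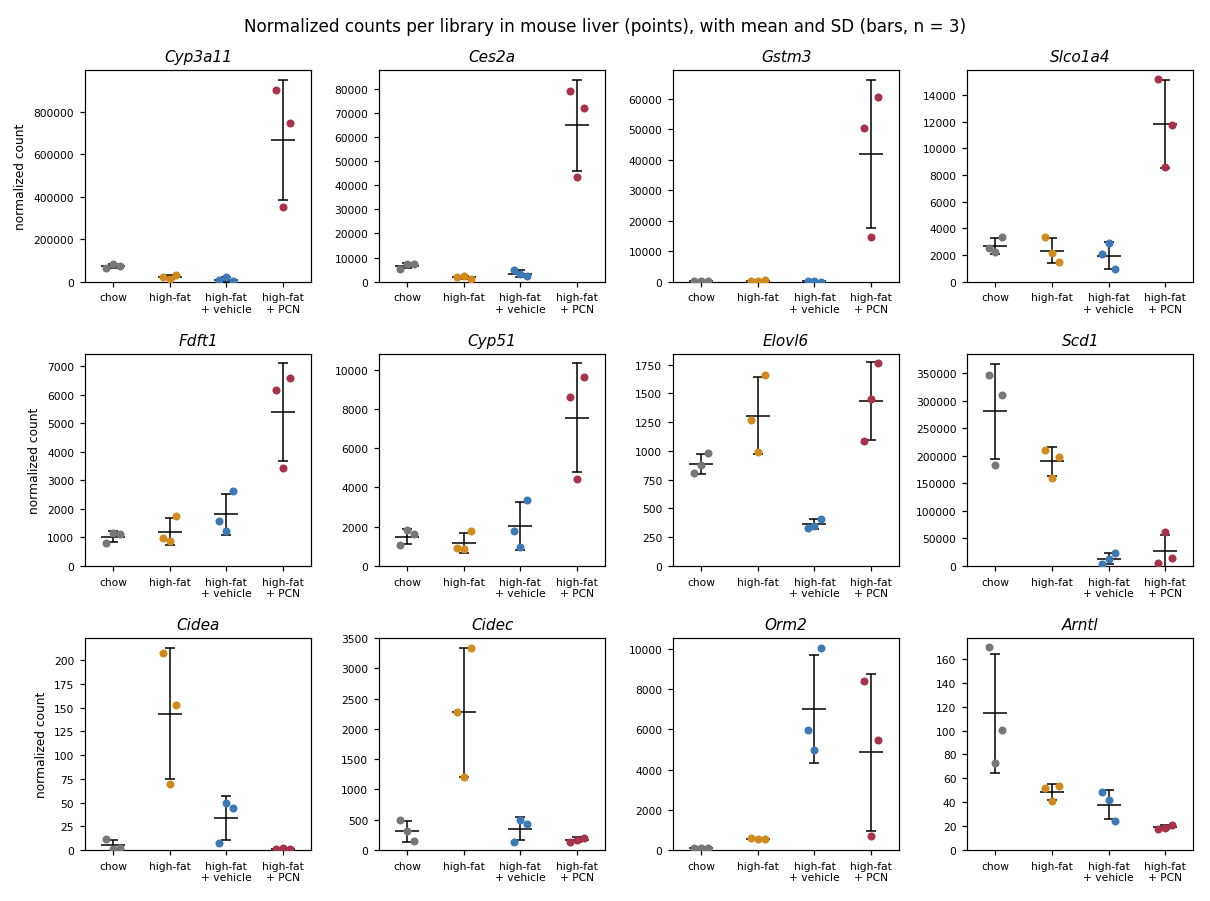
Normalized read counts of 12 genes in each liver library (points), with the group mean and SD (bars, n = 3), for chow, high-fat diet, vehicle and PCN, on linear axes from 0. Cyp3a11 averaged 668281 with PCN and 10422 with vehicle, and Cidea averaged 144 in uninjected high-fat-diet livers and 1.3 with PCN.

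The high-fat diet without injection was compared with chow. Cidea rose 29.2-fold, from 4.9 ± 5.5 normalized counts in chow livers to 144 ± 69.2, and 82.3-fold without chow replicate 8. Cidec, its relative in droplet enlargement, rose 7.25-fold from 314 ± 174 to 2274 ± 1065. Col1a1, a collagen chain made by activated stellate cells, rose 8.74-fold from 59.2 ± 20.7 to 518 ± 63.3, and Col3a1 rose 5.49-fold. Lcn2, an iron-binding acute phase protein, rose 10.3-fold from 259 ± 102 to 2658 ± 461, and Orm2 rose 4.67-fold. The lipogenic regulator Thrsp rose 7.83-fold, Srebf1 rose 2.84-fold and Fasn rose 2.22-fold. Scd1, which makes monounsaturated fatty acids, was not called at 189614 ± 26416 against 280617 ± 85931 in chow. Ces2a fell 3.5-fold and Cyp3a11 fell 3.47-fold, from 74569 ± 10266 to 21520 ± 9430. The Cidea gene (ENSMUSG00000024526) spans positions 67343564 to 67367794 of chromosome 18, and the Col1a1 gene (ENSMUSG00000001506) spans positions 94936224 to 94953042 of chromosome 11.

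Of 22 lipid droplet genes 10 rose with the diet and 0 fell, including Plin4, Fabp4 and Cd36 (adjusted p = 3.37e-05, exact). Of 23 fatty acid synthesis genes 6 rose and 0 fell (adjusted p = 0.0267, exact). Of 31 acute phase genes 12 rose and 1 fell, with Saa1 4.97-fold and Hp 1.55-fold higher (adjusted p = 7.15e-06, exact). Markers of some non-parenchymal cells rose as well. Of 24 stellate cell and fibrosis markers 12 rose and 0 fell (adjusted p = 5.35e-06, exact). Of 23 macrophage markers 11 rose and 0 fell, among them Adgre1 (1.72-fold), C1qc (1.73-fold) and Trem2 (4.6 ± 0.9 to 22.5 ± 15.5 normalized counts; adjusted p = 7.69e-06, exact). In edgeR 0 of these 11 macrophage markers (11 at an unadjusted p under 0.05) and 3 of the 12 stellate markers passed. Of 6 cholangiocyte markers 3 rose (Spp1, Krt23 and Pkhd1; adjusted p = 0.0267, exact), with Spp1 2.60-fold higher without high-fat-diet replicate 38 and 4.10-fold higher with it. The macrophage, stellate, endothelial and cholangiocyte lists shared 0 genes with the other lists. Endothelial markers had 1 riser and 1 faller of 16, and 0 of 7 lymphocyte and granulocyte markers were called by the authors' DESeq2 test. The cell cycle genes Mki67 and Top2a were among 8 of 25 that rose (adjusted p = 0.00313, exact).

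Of the 30 phase I enzymes 4 rose and 7 fell with the diet, the fallers including Cyp3a44 (3.59-fold), Cyp2c55 (2.10-fold) and Cyp2c50 (2.0-fold; adjusted p = 9.93e-05, exact). Phase II enzymes split 3 up and 4 down of 32 (adjusted p = 0.035, exact), and NRF2 genes 4 up, with Nqo1, and 1 down, Gsr, of 18 (adjusted p = 0.0333, exact). Lipoprotein genes gave 1 riser, Apoa4 (5.86-fold), and 5 fallers, including Apom, Lipc and Mttp, of 23 (adjusted p = 0.0267, exact). Amino acid genes gave 2 up and 5 down of 28, with Agxt, Gnmt and Cbs lower (adjusted p = 0.0261, exact). Of 36 PPARα target genes 2 rose and 5 fell, including Acot1 (2.78-fold) and Cyp4a10 (2.68-fold), and the list did not pass (adjusted p = 0.0595, exact). Cholesterol synthesis genes had 2 risers and 1 faller of 26 (adjusted p = 0.525, exact), with Fdft1 not called at 1197 ± 471 against 1027 ± 188 counts in chow. Of the 25 lists 14 passed with the diet, and 9 passed among genes with a mean count of at least 50. Those lost were phase II (adjusted p = 0.0542, exact), fatty acid synthesis (0.0523), lipoprotein (0.0523), amino acid (0.0854) and cholangiocyte genes (0.0542).

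The 1226 genes of the diet comparison were 709 higher and 517 lower with high-fat diet. The edgeR test of their counts passed 101, including Orm2, Col1a1, Col3a1, Lcn2, Thrsp and Cidea. The edgeR count was 28, 8 and 13 without chow replicates 8, 17 and 19, and 2, 53 and 18 without high-fat-diet replicates 4, 30 and 38.

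Injection of the vehicle (30% DMSO in corn oil) was compared with no injection within the high-fat diet, where values of all genes were at hand. Orm2, an acute phase glycoprotein, was the 1 gene of 13775 that passed edgeR, 12.2-fold higher at 7004 ± 2686 normalized counts against 573 ± 12.6 (adjusted p = 0.0211, edgeR). The Orm2 gene (ENSMUSG00000061540) spans positions 63362449 to 63365878 of chromosome 4. Saa1 stood 13.7-fold higher (70410 ± 45100 against 5123 ± 1907), Itih3 4.20-fold and Itih4 4.19-fold higher, all 3 past the authors' deposited DESeq2 test and not past edgeR. Scd1 stood 14.5-fold lower (13088 ± 10462 against 189614 ± 26416; 24.5-fold without vehicle replicate 55), Elovl6 3.60-fold, Cidec 6.43-fold and Cidea 4.23-fold lower, also past the deposited test alone. Cyp3a11 was not called, at 10422 ± 9760 against 21520 ± 9430.

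The number of genes called between vehicle and no injection differed between tests. At an unadjusted p under 0.05 edgeR counted 1725 genes, while an adjusted p under 0.05 was met by 206 genes in the deposited DESeq2 results (73 higher and 133 lower with vehicle) and by 201 in a DESeq2 refit. Without an expression filter edgeR called 283 genes (97 higher and 186 lower with vehicle). Without vehicle replicate 23 edgeR called 9 genes, and it called 0 without high-fat-diet replicate 4, 30 or 38 or without vehicle replicate 15.

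Gene groups were tested in the vehicle comparison as well. Of 31 acute phase genes 12 rose and 0 fell at the deposited test (adjusted p = 2.31e-13, exact), and camera, a test of a list against the other genes, gave a median log2 ratio of 1.05 (adjusted p = 6.92e-27, or 0.258 with an estimated correlation). Of 23 fatty acid synthesis genes 8 fell and 0 rose (adjusted p = 1.05e-08, exact), with a median of -0.74 (camera adjusted p = 3.13e-16, or 0.258 with an estimated correlation). Of 22 lipid droplet genes 6 fell and 0 rose (adjusted p = 5.09e-06, exact), with a median of -0.55 (camera adjusted p = 1.99e-13, or 0.258 with an estimated correlation). The deposited calls also held 4 phase II genes of 32, all lower (adjusted p = 0.00769, exact), and 3 cell cycle genes of 25, 1 higher and 2 lower (adjusted p = 0.0292, exact, and 0.109 among genes with a mean count of at least 50). Adjusted over the list alone, edgeR passed 15 of 30 acute phase, 9 of 23 fatty acid synthesis, 10 of 22 lipid droplet and 8 of 24 stellate cell genes.

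Camera called 15 of the 25 lists, 0 of them with an estimated correlation and 0 by fry for a common direction, whose lowest adjusted p was 0.106. Fry for changes in either direction, which does not compare a list with other genes, passed 12 lists, with an adjusted p of 0.0221 for fatty acid synthesis and 0.0313 for acute phase genes. Stellate cell (median -0.61), macrophage (-0.42) and endothelial (-0.32) markers, cytokine and interferon genes (-0.56), cell cycle genes (-0.75) and a list of blood, adipose, muscle and pancreas transcripts (-0.63, 7 genes) were lower with vehicle. Their camera adjusted p ran from 2.68e-11 for stellate markers to 0.00102 for macrophage markers (0.258 and 0.621 with an estimated correlation). With an estimated correlation endothelial markers had 0.408, and the cytokine, cell cycle and blood and adipose lists 0.258. PPARα targets (-0.25), phase II enzymes (-0.17) and NRF2 genes (-0.40) were lower, at camera adjusted p = 6.56e-06, 0.00061 and 0.00615 (0.42, 0.621 and 0.408 with an estimated correlation). Cholesterol synthesis (0.42), clock (0.26) and nuclear receptor genes (0.21) were higher, at camera adjusted p = 0.00739, 0.0209 and 0.000132 (0.79, 0.258 and 0.258 with an estimated correlation). Single libraries decided 5 of these 15 calls. The cholesterol list was lost without high-fat-diet replicate 4 (0.0583), replicate 30 (0.0873) or vehicle replicate 55 (0.871), and the macrophage list without high-fat-diet replicate 38 (0.412) or vehicle replicate 55 (0.142). The phase II list was lost without vehicle replicate 55 (0.381), the NRF2 list without high-fat-diet replicate 38 (0.0712) or vehicle replicate 15 (0.0843), and the clock list without high-fat-diet replicate 30 (0.0556) or vehicle replicate 15 (0.0649). Phase I enzymes did not pass with all libraries (limma camera adjusted p = 0.926). They passed camera without vehicle replicate 23 (0.01) or vehicle replicate 55 (0.0201), and passed fry for either direction (0.04). Bile acid genes, which did not pass either (0.0687), passed camera without high-fat-diet replicate 4 (0.0186). In 5 lists that did not pass, namely phase I enzymes, gluconeogenesis, glycolysis and insulin genes, cholangiocyte markers, endoplasmic reticulum stress and sex-biased genes, the median and the direction of the test had opposite signs. For drug and bile salt transporters the mean (0.09) and the test, which was downward, did.

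**Figure D2:**
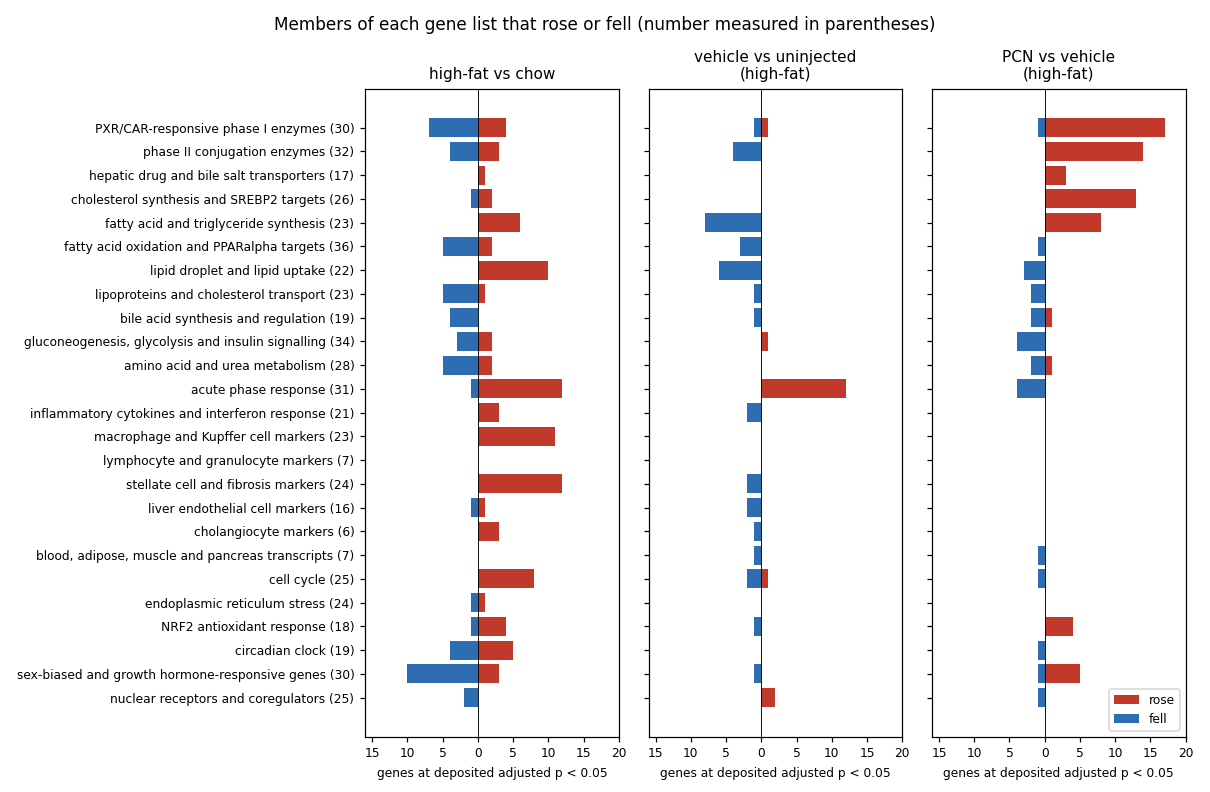
Number of genes of each of 25 gene lists that rose or fell at a deposited adjusted p under 0.05 in 3 comparisons, with the number measured in parentheses. Between PCN and vehicle 17 phase I, 14 phase II and 13 cholesterol synthesis genes rose, and between high-fat diet and chow 12 stellate cell and 11 macrophage markers rose.

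PCN against the uninjected high-fat diet contains the injection as well as the compound. Ces2a rose 34.3-fold, Cyp3a11 31.1-fold and Gstm3 117-fold over uninjected livers. Cyp51 rose 6.41-fold and Sqle 6.85-fold (13.4-fold without high-fat-diet replicate 38), and of 26 cholesterol synthesis genes 23 rose, 0 fell and 3 did not pass (adjusted p = 1.69e-24, exact). Cidea fell 113-fold, from 144 ± 69.2 to 1.3 ± 0.4 normalized counts (573 counts in all against 4; 95% interval of the pooled ratio 51.0 to 484). Cidec fell 13.5-fold from 2274 ± 1065 to 168 ± 40.3, and Mogat1, a triglyceride-building acyltransferase, fell 6.11-fold. Of 22 lipid droplet genes 11 fell and 0 rose, including Plin2, Cd36 and Fabp4 (adjusted p = 6.07e-08, exact). G6pc, the last enzyme of glucose output, fell 9.47-fold from 3697 ± 1604 to 390 ± 255, and Pck1 fell 2.22-fold, 2 of the 7 gluconeogenesis, glycolysis and insulin genes of 34 that fell while 2 rose (adjusted p = 0.000438, exact).

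Phase II enzymes rose in 21 of 32 cases and fell in 0 (adjusted p = 8.3e-18, exact), and phase I enzymes gave 16 risers and 2 fallers of 30 (adjusted p = 1.89e-14, exact). Acute phase genes gave 7 risers and 1 faller of 31 in PCN over uninjected livers, Orm1 4.98-fold, Apcs 5.32-fold and Itih3 2.50-fold higher (adjusted p = 0.000959, exact). Of 36 PPARα targets 7 fell and 0 rose, with Pdk4 2.38-fold and Cyp4a14 2.28-fold lower (adjusted p = 0.0118, exact). Lipoprotein genes gave 3 up and 4 down of 23, Apoa4 being 5.04-fold lower (adjusted p = 0.000861, exact), and sex-biased genes 6 up and 3 down of 30, with Mup20 2.06-fold lower (adjusted p = 0.000176, exact, and 0.175 among genes with a mean count of at least 50). Col1a1 fell 2.29-fold and was 1 of 3 stellate markers of 24 that fell (adjusted p = 0.289, exact), and 1 of 23 macrophage markers fell. The 809 genes were 487 higher and 322 lower with PCN. The edgeR test passed 139, with 0, 22 and 56 without high-fat-diet replicates 4, 30 and 38, and 20, 171 and 0 without PCN replicates 5, 11 and 27.

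Vehicle-injected high-fat-diet livers were also set against chow. Orm2 rose 57.2-fold, from 122 ± 5.5 to 7004 ± 2686 normalized counts, and Saa1 rose 68.4-fold, from 1030 ± 336 to 70410 ± 45100. Scd1 fell 21.4-fold (36.2-fold without vehicle replicate 55) and Cyp3a11 fell 7.15-fold (15.5-fold without vehicle replicate 23). Nr1i2, which encodes PXR, rose 1.46-fold, from 1522 ± 177 to 2221 ± 235, and was called in that 1 of the 6 tables. Of 31 acute phase genes 17 rose and 0 fell (adjusted p = 1.85e-12, exact), and of 36 PPARα targets 11 fell and 0 rose, with Cyp4a10 3.26-fold and Acot1 3.86-fold lower (adjusted p = 2.25e-05, exact). Fatty acid synthesis genes gave 2 risers, with Srebf1, and 7 fallers, with Elovl6, of 23 (adjusted p = 2.25e-05, exact). Phase I enzymes gave 5 up and 5 down of 30 (adjusted p = 2.25e-05, exact), phase II 1 up and 5 down of 32 (0.0266), amino acid genes 1 up and 5 down of 28 (0.0153) and nuclear receptors 5 up and 0 down of 25 (0.0336, and 0.0575 among genes with a mean count of at least 50). Cholangiocyte markers passed in that restricted set alone (0.0364, and 0.0948 otherwise). The 790 genes were 439 higher and 351 lower with vehicle. The edgeR test passed 85, with 3, 1 and 2 without chow replicates 8, 17 and 19, and 14, 48 and 9 without vehicle replicates 15, 23 and 55.

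PCN-treated high-fat-diet livers differed from chow in the most genes, 1112 higher and 920 lower. Cyp3a11 rose 8.96-fold over chow, Ces2a 9.79-fold, Gstm3 312-fold and Abcb1a 12.4-fold. Cyp51 rose 5.06-fold over chow and Fdft1 5.26-fold. Of 26 cholesterol synthesis genes 25 rose and 0 fell (adjusted p = 6.95e-19, exact). Cyp4a14 fell 5.10-fold and Cyp4a10 fell 4.35-fold among 13 PPARα targets of 36 that fell with 0 rising (adjusted p = 0.00266, exact). Amino acid genes gave 14 fallers and 3 risers of 28, with Tat 2.55-fold and Ass1 1.94-fold lower (adjusted p = 1.32e-07, exact), and lipoprotein genes 11 fallers and 3 risers of 23 (adjusted p = 1.86e-06, exact). Bile acid genes gave 7 fallers, with Cyp7b1 2.13-fold lower, and 2 risers of 19 (adjusted p = 0.00175, exact), and gluconeogenesis, glycolysis and insulin genes 11 fallers and 1 riser of 34 (adjusted p = 0.00433, exact). Col1a1 rose 3.82-fold and Col3a1 3.20-fold over chow, 2 of 8 stellate markers of 24 that rose (adjusted p = 0.0288, exact, and 0.172 among genes with a mean count of at least 50). NRF2 genes gave 7 risers and 0 fallers of 18 (adjusted p = 0.0186, exact, and 0.0734 among genes with a mean count of at least 50). The edgeR test passed 771 of the 2032 genes, with 149, 140 and 172 without chow replicates 8, 17 and 19, and 144, 702 and 200 without PCN replicates 5, 11 and 27.

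Genes called in 2 comparisons were counted per direction against the number expected for independent lists among 13867 genes. The diet comparison and the PCN against vehicle comparison share no library. They had 98 genes in common, including 41 lower with the diet and higher with PCN, such as Cyp3a11, Ces2a, Cyp3a44, Cyp2c55 and Tm7sf2, where 10.3 were expected (p = 2.72e-14, Fisher's exact test). Of these 41, 21 were ribosomal protein genes, which moved together, and the test treats genes as independent. Another 21, such as Cidea and Plin4, were higher with the diet and lower with PCN, where 8.5 were expected (p = 0.000113, exact). In the same direction were 25 genes higher in both, where 14.1 were expected (p = 0.00402, exact), and 11 lower in both, where 6.2 were expected (p = 0.0465, exact).

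The other pairs share 3 libraries each. PCN against vehicle and PCN against the uninjected diet shared 246 genes, 190 higher in both (9.7 expected) and 56 lower in both (3.9 expected), Cyp3a11 and Cyp51 being higher in both and Cidea lower in both. Chow against the uninjected diet and chow against vehicle shared 349 genes, 191 higher in both (22.4 expected), 153 lower in both (13.1 expected) and 5 in opposite directions (34.3 expected). Vehicle and PCN, each against the uninjected diet, shared 98 genes, 31 higher in both (2.6 expected), such as Orm2 and Itih3, and 60 lower in both (3.1 expected), such as Cidec and Mogat1, with 7 in opposite directions (6.4 expected). Orm2 stood at 8435, 682 and 5481 normalized counts in PCN replicates 5, 11 and 27, against 560 to 585 in uninjected libraries. In groups simulated without any difference against 3 shared libraries (8 simulations per pair), the log2 changes of the 2 comparisons correlated at a mean of 0.508, 0.504 and 0.507 across genes, in the order of these pairs. They shared, in the same direction, on average 140, 126 and 136 genes at an unadjusted p under 0.05. Such groups gave hardly any adjusted calls, so shared adjusted calls (at most 0, 0 and 1) are no reference for the counts above. With 3 shared libraries a split into separate controls was not possible, so part of each excess may come from those libraries.

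**Figure D3:**
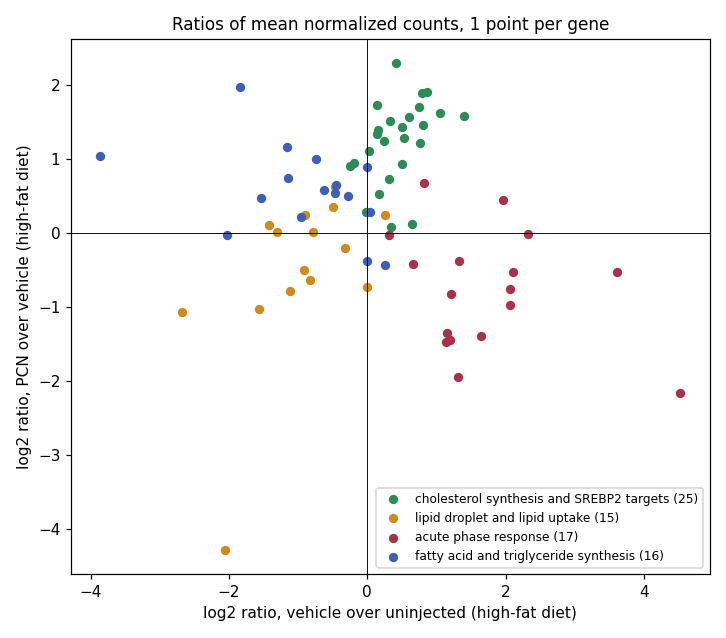
Log2 ratio of vehicle over uninjected livers (horizontal) against log2 ratio of PCN over vehicle livers (vertical) for single genes of 4 lists, limited to genes with counts in the PCN libraries. All 25 cholesterol synthesis genes shown lie above 0 on the vertical axis (median 1.34). All 17 acute phase genes shown lie to the right of 0 on the horizontal axis (median 1.33). PCN counts were at hand only for genes called in a comparison with PCN, so the genes shown were selected. Hamp2 (-0.73) and A2m (-0.01) are acute phase genes not shown, and the median over 30 acute phase genes was 1.05.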

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

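The edgeR test of listed genes, the deposited adjusted p as an alternative in the vehicle comparison, DESeq2 with independent filtering and no prior, and fry for either direction were chosen only after the data were seen. Comparisons are given in the order high-fat diet over chow, PCN over vehicle, PCN over uninjected, vehicle over chow and PCN over chow. An adjusted p under 0.01 left 650, 230, 512, 465 and 1315 genes, and an absolute log2 change of at least 1 left 334, 170, 298, 296 and 642, fewer by construction. The edgeR test passed 101, 15, 139, 85 and 771 of the listed genes, and the cause was not tested. Leaving out 1 library, which also leaves fewer samples, moved these edgeR counts to 2 to 53, 0 to 23, 0 to 171, 1 to 48 and 140 to 702. Without PCN replicate 11 the count rose from 15 to 23 (PCN over vehicle) and from 139 to 171 (over uninjected). It fell from 771 to 702 over chow. Of 372 named gene values 372 kept their direction under edgeR and 151 passed, but genes selected as called could hardly change direction. In the comparison of vehicle and no injection, the 1 edgeR gene, Orm2, became 0 at an adjusted p under 0.01, and leaving out 1 library gave 0 to 9 genes. DESeq2 gave 201 genes, DESeq2 with independent filtering and no prior 268, the deposited adjusted p 206 and Benjamini-Hochberg adjustment of the deposited raw p 206. Without an expression filter edgeR gave 283 genes, where its median prior degrees of freedom were 22 against 3.9 with the filter, and the cause was not tested further. Lists passing there fell from 15 to 5 with Fisher's test of deposited calls, 0 with an estimated correlation and 0 by fry for a common direction, while fry for either direction passed 12, and without single libraries 13 to 17 passed. With members of mean count of at least 50, 9 lists in place of 14 passed in the diet comparison, and over the 6 comparisons 11 list calls of Fisher's test were lost and 1 gained. Shared calls fell, at an adjusted p under 0.01 and at an absolute log2 change of at least 1 in both, to 187 and 95 (diet and vehicle over chow), 136 and 90 (PCN over uninjected and over vehicle), 56 and 44 (vehicle and PCN over uninjected) and 33 and 19 (diet over chow and PCN over vehicle). Not run, since chow and PCN counts were at hand only for listed genes, were 1 fit over the 12 samples and, in the 5 tables of called genes, a DESeq2 refit, no filter and a new adjustment of the deposited p. Depth was lowest at 7466378 counts in high-fat-diet replicate 38, and its effect on detection was not tested. With 3 samples per group 27.3% of simulated 2-fold changes were recovered.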

Other observations

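The tests of explanations and the ribosomal and respiratory gene groups were chosen only after the results were seen, except the test that left out single PCN libraries, while the tests of the clock and sex-biased lists were chosen beforehand. Genes for cytosolic ribosomal proteins, gathered by name after their values were seen, fell with the diet and rose with PCN in some comparisons. Of 79 measured, 31 fell and 0 rose with high-fat diet over chow, 47 rose and 0 fell with PCN over vehicle, and 74 rose and 0 fell with PCN over uninjected livers. With PCN over chow 46 rose and 0 fell, 1 of them past edgeR, and with vehicle over chow the deposited DESeq2 test called 0, so the fall with the diet was not called in injected livers. In the authors' deposited table the median log2 change of the called ones was -0.40, 0.70 and 0.81 in turn. Rps18, for example, averaged 4241 ± 489 normalized counts in chow, 3140 ± 136 with high-fat diet, 3653 ± 614 with vehicle and 6487 ± 765 with PCN (SD, n = 3). They made up 21 of the 41 genes that were lower with the diet and higher with PCN. In edgeR 25 of the 74 passed, and 0 of the 47 and 0 of the 31. Between vehicle and no injection the deposited DESeq2 test called 0 of the 79, edgeR called 0 and their edgeR median log2 change was 0.14. Of 76 nuclear-encoded respiratory chain genes the deposited test called 0 between PCN and vehicle and 0 between PCN and uninjected livers, and edgeR counts of these genes were not at hand for PCN.

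Clock genes differed between chow and the other groups. Arntl (BMAL1), a core activator, averaged 114 ± 49.9 normalized counts in chow, 48.5 ± 6.8 with high-fat diet, 38.1 ± 12.3 with vehicle and 19.1 ± 1.5 with PCN, while the repressor gene Per3 averaged 238 ± 58.8, 601 ± 329, 922 ± 319 and 873 ± 260 (SD, n = 3). Of 19 clock genes 5 rose and 4 fell with high-fat diet over chow (adjusted p = 5.46e-05, exact), 5 rose and 3 fell with vehicle over chow (2.3e-05), and 4 rose and 6 fell with PCN over chow (0.000322). The hour at which livers were taken is not in the labels. Sex-biased genes also moved with the diet, Cyp2b9 68.2-fold higher (188-fold without chow replicate 8) and Cyp4a12b 16.6-fold lower (32.9-fold without high-fat-diet replicate 30), in a list with 3 risers and 10 fallers of 30 (adjusted p = 6.77e-06, exact). Elovl3 was 3.98-fold and Mup20 1.95-fold lower with the diet. With PCN over chow the list had 8 risers and 13 fallers (adjusted p = 6.56e-11, exact).

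Acute phase genes stood higher in vehicle-injected than in uninjected livers, with a median log2 ratio of 1.05 over 30 genes (bootstrap SE 0.22). The low depth of high-fat-diet replicate 38 alone is argued against, since the median was 0.97 without it (SE 0.23). Macrophage markers were not higher in the vehicle livers. The median of the 23 markers, as log2 ratios of group means, was -0.47 (SE 0.07, and -0.42 as edgeR log2 changes). That SE is over genes, not livers. The camera adjusted p of the list was 0.621 with an estimated correlation, 0.412 without high-fat-diet replicate 38 and 0.142 without vehicle replicate 55. More macrophages in the vehicle livers are thus not excluded. Without vehicle replicate 55 the acute phase median was 0.60 (SE 0.22, over genes). Camera at the preset correlation still passed the list without that library (adjusted p = 1.9e-25). With an estimated correlation and all libraries the list did not pass (0.258). The rise was thus not seen in vehicle replicate 55 alone. How much of the median comes from a strong response of that library cannot be told apart from a response of the group. An acute phase response to the injections or the DMSO vehicle may be a source, and no sample separates the injection from what was injected. Of the 10 splits of the 6 libraries, the real one gave 1 gene in edgeR and the highest other 0, and 10 splits are too few for a share under 0.05.

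Cholesterol synthesis genes were higher with PCN. An effect of injection alone is argued against by the median log2 ratio of 1.34 between PCN and vehicle over the 25 of 26 genes with PCN counts (bootstrap SE 0.12), which was 0.41 between vehicle and no injection. That SE is over genes of 1 pathway, not livers, and the genes had PCN counts because they were called in a comparison with PCN. Vehicle libraries were not left out in turn for this median, and 1 of the 13 risers between PCN and vehicle passed edgeR. A single PCN library is argued against, as the median ran from 1.22 without PCN replicate 27 to 1.47. An effect of PCN on cholesterol synthesis, perhaps through SREBP2, is a hypothesis from these same data, and food intake and the hour of sampling were not tested.

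Of the lipid droplet genes, 11 were lower in PCN-treated than in uninjected livers, with a median log2 ratio of -1.42. Their separate medians were -1.11 between vehicle and no injection and -0.50 between PCN and vehicle (bootstrap SE 0.30). These genes were selected on the uninjected and the PCN libraries. The first of those medians uses the uninjected libraries again and the second the PCN libraries, so both lean toward a fall. The injection and PCN thus cannot be told apart as sources. Over the 15 list genes with counts in both steps the medians were -0.90 and -0.20, and 7 of the 15 stood higher with PCN than with vehicle. Fat tissue in the uninjected samples is argued against. Adipoq stood at 0.0597% of Cfd, with means of 0.2 ± 0.3 and 277 ± 101 normalized counts, and Plin1 stood at 0.9 ± 1.0 (SD, n = 3). Cidea, Plin4 and Fabp2 passed the authors' DESeq2 test between PCN and vehicle, and 0 of these 3 passed edgeR. A share of the fall of these genes may belong to PCN, on the deposited test alone.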
